A study of Homo sapiens with 10 samples.

How the data were processed

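RNA was measured in 10 libraries of cardiac organoids, 5 treated with DMSO and 5 with nifedipine for 8 h. Groups were taken from the treatment label, and the letter-number codes of the samples name libraries and pair nothing. Libraries were made with a stranded polyA kit, per the labels' protocols. The authors deposited expected counts per gene, which are estimated read counts that need not be whole, and STAR 2.7.9a, RSEM 1.3.1 and GRCh38 are named per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so the values of antisense and overlapping genes are uncertain. Expected counts divide reads that fit several genes between them, which makes the values of close paralogs less certain.

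The table held 61552 genes and 0 entries without a gene, and 6.00% of values were not whole. Counts were rounded to whole numbers before testing. Symbols came from the file for 35257 genes and from a table of gene names for 8641. Where several IDs shared a symbol, the ID with the highest mean over all libraries took it, and 1303 others kept their ID. Of the genes tested, 94.9% had a symbol. Positions came from GENCODE release 29 on GRCh38, which held all 118 named genes.

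Genes were filtered with filterByExpr by group, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3; estimateDisp, glmQLFit with robust estimation, glmQLFTest) with no covariate, at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 change was derived as its size divided by the square root of the F statistic. The 95% intervals used this SE with normal quantiles, which can make them too narrow with few libraries per condition. CPM values use TMM-scaled library sizes, and principal components used a prior count of 1. The 31 gene lists, with 680 genes, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 31 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its own genes move one way on balance. Of 11 lists past 0.05 with camera, 3 passed with an estimated correlation (hypertrophy, sarcomere and calcineurin-NFAT). With fry 9 passed, those other than YAP-TEAD targets and endoderm markers. Permutation tests of library measures ran over all divisions of the 10 libraries.

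Named genes were the 12 with the highest and 12 with the lowest fold change among genes past the threshold with a mean log2 CPM of at least 1, a symbol and groups that did not overlap, 10 genes chosen in advance, and the 4 members of smallest p from each list with a member past the threshold. Genes named outside this rule were chosen after their values were seen: TCAP, XIRP2, CCN2, PPP3CA, CABIN1, FOS, EGR1, ATP2A2, RYR2, KCNH2, PDGFRB, RGS5, CD68, CSF1R, SRF, MAP2K6, PEG10 and those of the closing section's families. The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals alone, no filter beyond 1 count, at least 50 counts in 5 libraries, 1 surrogate variable (sva 3.50.0), adjusted p under 0.01 or 0.1, a test against a fold of 1.2, and leaving out each library. Added after seeing the data were fits without DMSO G3 and nifedipine D7, with the macrophage marker level, and with the number in the sample code as a covariate. Counting the codes down columns of 8 gave the sequencer's sample number in all 10 libraries.

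The steps were tested on simulated counts for the nifedipine and DMSO comparison, drawn 20 times with 200 changed genes among a median of 15498.5 genes tested. They recovered 31.0% of genes changed 1.25-fold, 65.0% of those changed 1.5-fold, 83.8% at 2-fold and 95.5% at 3-fold, with 0 of wrong sign. False calls made up 6.75% of calls over the runs, from 1.47% to 11.1% per run, above the nominal level. In a further simulation over 15497 genes with the G2/M list raised 1.3-fold, camera called 1 of 31 lists, the raised one. Genes were drawn independently, so this run could not show false list calls that come from members varying together. Pairs of libraries were compared by chi-square over genes with at least 10 counts. Nifedipine dose and organoids per sample are not given in the sources used here.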

Results

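Human cardiac organoids made from HES3, an established human embryonic stem cell line, were exposed for 8 h to nifedipine, a dihydropyridine that blocks L-type calcium channels, or to the DMSO vehicle. PolyA-selected RNA was sequenced from 5 libraries per condition, 10 in all. The comparison asks which transcripts differ soon after channel block, in a study concerned with cardiomyocyte proliferation and calcineurin, a calcium-dependent phosphatase. Rounded expected counts summed to between 5961891 (DMSO E10) and 9212774 (DMSO B9) per library. Group means were 8168438 ± 1290173 (SD, n = 5) with DMSO and 7378050 ± 926430 (SD, n = 5) with nifedipine, with an exact two-sided permutation p of 0.325. Nothing in the labels says that the libraries of a condition came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

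Cardiac stretch and contractile transcripts fell with nifedipine, and a smaller set of genes rose. NPPB, which encodes the natriuretic peptide BNP, fell from 15.9 ± 4.37 to 1.93 ± 0.557 CPM (SD, n = 5), a log2 change of -3.02 ± 0.22 (SE). RRAD, a small GTPase that inhibits L-type calcium channels, fell from 116 ± 21.2 to 32.7 ± 3.38 CPM (SD, n = 5). KCNS2, a modifier subunit of voltage-gated potassium channels, rose from 2.04 ± 0.713 to 7.59 ± 0.539 CPM (SD, n = 5). Of 15739 genes tested, 253 were higher and 463 were lower with nifedipine in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 21 higher and 32 lower genes changed at least 2-fold, and the median fold was 1.31 in each direction. All 5 nifedipine libraries lay above all 5 DMSO libraries for 186 of the higher genes and below them for 371 of the lower genes. Over all tested genes 5.58% had groups that did not overlap, where chance gives 0.794%. With library totals alone as the scaling, 521 genes were higher and 304 lower, or 63.2% higher against 35.3%. The count of higher genes was 158 without DMSO D6 and 156 without nifedipine G9.

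**Figure D1:**
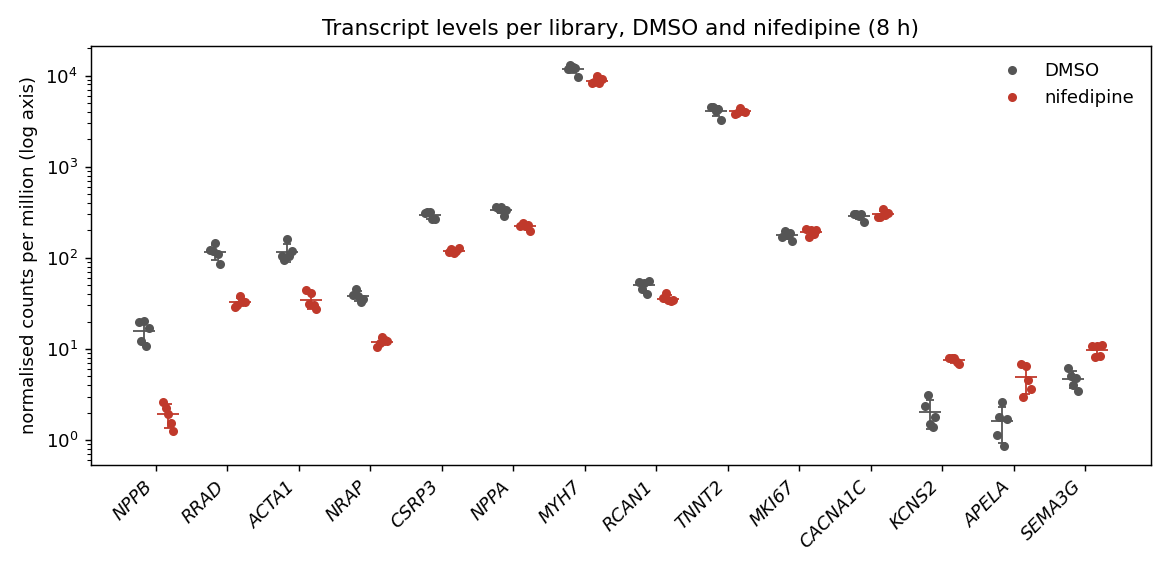
Normalised CPM on a log axis for 14 genes, with 1 point per library and bars for the mean ± SD of 5 libraries. NPPB falls from a mean of 15.9 to 1.93 and KCNS2 rises from 2.04 to 7.59, while TNNT2 means are 4131 with DMSO and 4035 with nifedipine, a log2 change of -0.03 that turns to 0.02 with library totals alone.

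Genes known to respond to cardiac stretch and hypertrophic load were lower as a group. Of 19 measured members of this list, 13 fell, 0 rose and 6 did not pass the test, and 14 fell and 0 rose adjusted over the list alone. CSRP3, the muscle LIM protein of the Z-disc, fell from 296 ± 27.1 to 119.9 ± 5.50 CPM (SD, n = 5). NRAP, an actin-binding protein of myofibril assembly, fell by 1.68 on the log2 scale (SE 0.10), and ANKRD1, a stretch-responsive titin-binding protein, fell by 1.21 (SE 0.18). NPPA, which encodes the natriuretic peptide ANP, fell from 339 ± 30.8 to 223 ± 16.6 CPM (SD, n = 5). CCN2 had a log2 value of -0.51 ± 0.23 (SE) and did not pass. The list median was -0.56, with a camera adjusted p of 8.36e-52 at the preset correlation and an adjusted p of 5.17e-06 with an estimated correlation. The gene lists overlap: hypertrophy and sarcomere share 3 genes, and hypertrophy and calcineurin-NFAT share 5.

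Sarcomere genes fell unevenly. Of 30 measured members, 18 fell, 0 rose and 12 did not pass the test, and 21 fell and 0 rose adjusted over the list alone. ACTC1, the cardiac alpha-actin gene, fell from 3760 ± 346 to 1657 ± 57.3 CPM (SD, n = 5). The skeletal alpha-actin gene ACTA1 fell by 1.75 on the log2 scale (SE 0.19), TCAP, which encodes telethonin, by 1.12 (SE 0.10), and MYH7, the beta-myosin heavy chain gene, by 0.42 (SE 0.08). The alpha-myosin gene MYH6 (-0.04 ± 0.07, SE) and the troponin T gene TNNT2 (-0.03 ± 0.08, SE) did not pass the test, and both had a value of 0.02 with library totals alone. Leaving out DMSO B9 also turned the TNNT2 value to 0.00020. The list median was -0.36, with a camera adjusted p of 3.54e-62 and an adjusted p of 0.00936 with an estimated correlation. Sarcomere genes took 4.96% ± 0.442 of counts with DMSO and 4.04% ± 0.226 with nifedipine (SD, n = 5; exact two-sided permutation p = 0.0159). Actin genes and the MYH6 and MYH7 pair are close paralogs, so their separate values are uncertain.

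Of 14 smooth muscle and pericyte markers measured, 4 fell, 0 rose and 10 did not pass, and 5 fell and 0 rose adjusted over the list alone. CNN1, a smooth muscle calponin, fell by 0.87 on the log2 scale (SE 0.06), KCNMB1, a potassium channel subunit of smooth muscle, by 1.03 (SE 0.16), LMOD1 by 0.45 (SE 0.10) and SMTN by 0.27 (SE 0.06). The pericyte genes PDGFRB (-0.02 ± 0.12, SE) and RGS5 (-0.07 ± 0.07, SE) did not pass. The list median was -0.31, with a camera adjusted p of 2.00e-10 and an adjusted p of 0.137 with an estimated correlation.

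RCAN1, a calcineurin regulator whose transcription rises with calcineurin activity, fell from 49.8 ± 6.49 to 35.8 ± 2.997 CPM (SD, n = 5), a log2 change of -0.48 ± 0.09 (SE). Of 18 measured calcineurin-NFAT responsive genes, 6 fell, 0 rose and 12 did not pass, with the same counts of 6 and 0 adjusted over the list alone. The 6 were NPPB, ACTA1, MYH7, RCAN1, the orphan nuclear receptor gene NR4A1 (-0.90) and the actin-binding XIRP2 (-0.63). The list had a median of -0.26, a camera adjusted p of 8.80e-08 and an adjusted p of 0.00936 with an estimated correlation. Among 19 calcineurin components and partners, MYOZ2 (-0.42), AKAP6 (-0.40), RCAN1 and RCAN2 (-0.44) fell, 0 rose and 15 did not pass. MYOZ2 and AKAP6 bind calcineurin at the Z-disc and the nuclear envelope. The catalytic subunit gene PPP3CA had a value of 0.10 ± 0.08 (SE). For this list 4 fell and 1 rose adjusted over the list alone, the latter being CABIN1, a calcineurin inhibitor, at 0.19 ± 0.06 (SE). The list had a median of -0.12 and a camera adjusted p of 0.00847, and the adjusted p was 0.0720 with an estimated correlation. RCAN2 lost its call without DMSO A2, DMSO D6, DMSO E10, nifedipine B4 or nifedipine C1, with an adjusted p of at most 0.0583, and 1 component rose without nifedipine D12, with library totals alone or in DESeq2.

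Of 35 immediate early and activity genes measured, 8 fell, 0 rose and 27 did not pass, and 11 fell and 0 rose adjusted over the list alone. JUN, a subunit of the AP-1 transcription factor, fell from 94.8 ± 3.90 to 56.1 ± 3.47 CPM (SD, n = 5). The stress-induced factor gene ATF3 fell by 1.24 on the log2 scale (SE 0.19) and the phosphatase gene DUSP5 by 0.53 (SE 0.10). FOS (-0.19 ± 0.25, SE) and EGR1 (-0.32 ± 0.21, SE) did not pass. The list had a median of -0.26, a camera adjusted p of 1.13e-07 and an adjusted p of 0.137 with an estimated correlation. The count of lower genes was 5 without DMSO D6, nifedipine B4 or nifedipine G9, and 5 with library totals alone or in limma-voom.

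Calcium channel genes included 2 that rose. CACNA1D, which encodes the L-type subunit Cav1.3, rose from 24.4 ± 5.53 to 39.1 ± 4.36 CPM (SD, n = 5), and CACNA1G, of the T-type channel Cav3.1, rose from 230.1 ± 34.5 to 309.6 ± 21.4 CPM (SD, n = 5). CACNA1C, the main cardiac L-type subunit gene and a target of the drug, had a log2 value of 0.06 ± 0.07 (SE), with a 95% interval from -0.07 to 0.19, and -0.04 without DMSO G3 and nifedipine D7 together, an alternative chosen after seeing the data. Of 12 measured, 2 rose, 0 fell and 10 did not pass, and 4 rose and 0 fell adjusted over the list alone. The list's median was -0.02 while its mean was 0.10 and camera pointed upward, with an adjusted p of 0.0599. That adjusted p was 0.0265 without DMSO B9, 0.0445 without nifedipine G9, 0.00962 with at least 50 counts and 0.0225 with 1 surrogate variable, and ran from 0.00962 to 0.242 over the alternatives. CACNA1G lost its call without DMSO D6 (adjusted p = 0.0514 in edgeR), and 4 members rose without DMSO B9, without DMSO G3, with library totals alone or in DESeq2.

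Of 32 measured calcium handling genes, 6 fell, 0 rose and 26 did not pass, and 7 fell and 1 rose adjusted over the list alone. The sarcoplasmic reticulum calcium buffer CASQ2 fell from 174 ± 9.69 to 109 ± 3.44 CPM (SD, n = 5). JPH2, which ties the sarcoplasmic reticulum to the plasma membrane, fell by 0.54 on the log2 scale (SE 0.06), and the sodium-calcium exchanger gene SLC8A1 fell by 0.41 (SE 0.07). The calcium pump gene ATP2A2 (-0.09 ± 0.06, SE) and the ryanodine receptor gene RYR2 (0.16 ± 0.09, SE) did not pass. The list had a median of -0.09, a camera adjusted p of 1.15e-04 and an adjusted p of 0.138 with an estimated correlation. Without nifedipine D12 1 member rose, and with library totals alone 1 rose and 5 fell.

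Of 28 other cardiac ion channel and transporter genes, 2 rose, 3 fell and 23 did not pass, and 3 rose and 3 fell adjusted over the list alone. The connexin-40 gene GJA5 rose by 0.41 (SE 0.07), KCNJ4 fell by 0.92 (SE 0.15), KCND3 by 0.72 (SE 0.17) and ATP1B1 by 0.28 (SE 0.06). KCNH2, the other gene that rose, lost its call without DMSO D6, nifedipine D7 or nifedipine G9 (adjusted p of at most 0.0552 in edgeR), and KCND3 lost it without nifedipine G9 (0.0505). Without DMSO B9, 4 members rose. ATP1B1 had an adjusted p of 0.0586 with library totals alone. The list's median was 0.01, its mean was -0.05 and camera pointed upward with an adjusted p of 0.960. The mean was 0.011 with library totals and 0.0043 with at least 50 counts.

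Proliferation transcripts, which bear on the study's question, showed few changes at 8 h. MKI67, which encodes the proliferation antigen Ki-67, was at 177 ± 17.2 CPM with DMSO and 193 ± 15.8 with nifedipine (SD, n = 5), and the 95% interval of its log2 change ran from -0.01 to 0.26. Among 38 G1/S and DNA replication genes, 1 rose, the replication helicase gene MCM2 at 0.23 ± 0.07 (SE), 0 fell and 37 did not pass, and 0 changed adjusted over the list alone. Among 38 G2/M and mitosis genes, 0 rose, 37 did not pass and 1 fell, which was ANLN, an actin-binding protein of the cleavage furrow, at -0.44 ± 0.06 (SE). ANLN was also the 1 member that passed adjusted over the list alone. A positive log2 change was seen in 28 of the 38 G1/S genes and 21 of the 38 G2/M genes. At an unadjusted p under 0.05, 5 G1/S genes were higher and 1 lower, and 3 G2/M genes were higher and 1 lower. For the cell cycle inhibitors and p53 targets, 3 were higher and 3 lower. CCND1 had a value of -0.08 ± 0.05 (SE) and CDKN1A one of -0.18 ± 0.09 (SE), and neither passed. Of 25 cell cycle inhibitors and p53 targets, TP53INP1 rose by 0.26 (SE 0.06), 0 fell and 24 did not pass, and 3 rose and 2 fell adjusted over the list alone. Camera adjusted p-values were 0.130 for G1/S (median 0.05), 0.996 for G2/M (median 0.0020, mean -0.01) and 0.842 for the inhibitors (median -0.0013, mean -0.02), camera pointing upward in each.

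MCM2 kept its call without DMSO B9 and without nifedipine C1, and lost it in the other 8 fits that left out 1 library, with an adjusted p of at most 0.133 in edgeR, and also without DMSO G3 and nifedipine D7 together (0.153). It also lost it in limma-voom (adjusted p = 0.0655), where 0 G1/S genes rose, and with the macrophage marker level as a covariate (0.0757 in edgeR), a fit added after seeing the data. The G1/S list had a camera adjusted p of 0.0441 without DMSO B9 and 0.0388 without nifedipine C1, in a range from 0.0388 to 0.657 over the alternatives. The mean log2 change of G2/M genes was 0.011 without DMSO B9, 0.0083 without DMSO D6, 0.022 without nifedipine C1 and 0.00015 without nifedipine D12. That of cell cycle inhibitors was 0.012 without DMSO G3 and 0.00087 without nifedipine D7. Among cell cycle inhibitors 2 rose and 2 fell without DMSO B9, and 1 rose and 1 fell without nifedipine G9. With library totals alone 2 G1/S genes, 1 G2/M gene and 3 cell cycle inhibitors rose, and in DESeq2 2 inhibitors rose. The fit without DMSO G3 and nifedipine D7 together had 2 G2/M genes that fell.

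Of 30 oxidative phosphorylation genes, 5 fell, 0 rose and 25 did not pass, and 10 fell and 0 rose adjusted over the list alone. The 5 included the cytochrome c oxidase subunit genes COX5B (-0.24), COX7B (-0.25) and COX6A2 (-0.58). COX5B and COX7B lost their calls without nifedipine C1 (adjusted p of 0.0609 and 0.0530 in edgeR), and COX6A2 without DMSO D6, nifedipine C1 or nifedipine G9 (at most 0.0607). COX7B also lost it without DMSO G3 and nifedipine D7 together (0.0546). The list had a median of -0.11, a camera adjusted p of 6.07e-05 and an adjusted p of 0.148 with an estimated correlation. The count that fell was 1 without nifedipine C1, 2 without DMSO D6, 3 without DMSO A2, nifedipine B4 or nifedipine D12, 3 in limma-voom and 1 with library totals alone. Of 16 heat shock genes, the chaperone genes HSPB1 (-0.68 ± 0.07, SE), CRYAB (-0.31) and HSPA1A (-0.29) fell, 0 rose and 13 did not pass, with the same 3 and 0 adjusted over the list alone. This list had a median of -0.08, a camera adjusted p of 0.00390 and an adjusted p of 0.0634 with an estimated correlation. Of 20 YAP-TEAD targets, ANKRD1 (-1.21) and AJUBA (-0.23) fell, 0 rose and 18 did not pass, and 5 fell and 0 rose adjusted over the list alone. The median was -0.13 and the camera adjusted p was 0.00119, and the adjusted p was 0.242 with an estimated correlation and 0.0524 with fry. This list shares 2 genes with the hypertrophy list, ANKRD1 among them, so it is not a separate result. AJUBA lost its call without DMSO A2, DMSO D6, DMSO E10, nifedipine B4 or nifedipine G9 (adjusted p of at most 0.0821 in edgeR) and with library totals alone (0.106). HSPA1A has a near-identical paralog, so its value is uncertain.

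The 4 lipid and sugar metabolism lists held 1 or 2 genes that rose and at most 1 that fell. In fatty acid oxidation and PPAR targets the carnitine transferase gene CPT1A (0.42 ± 0.08, SE) rose and the fatty acid binding protein gene FABP3 (-0.51 ± 0.06, SE) fell, and 29 of 31 did not pass. In glycolysis and HIF targets ALDOC (0.36 ± 0.06, SE) rose, PFKP (-0.24 ± 0.06, SE) fell and 26 of 28 did not pass. In fatty acid synthesis GPAM (0.39 ± 0.09, SE) rose, ME1 (-0.41 ± 0.12, SE) fell and 13 of 15 did not pass. Each of these lists kept 1 that rose and 1 that fell adjusted over the list alone. In cholesterol biosynthesis HMGCS1 (0.22 ± 0.06, SE) and STARD4 (0.21 ± 0.05, SE) rose, 0 fell and 24 of 26 did not pass, with 2 and 0 adjusted over the list alone. Camera adjusted p-values were 0.470, 0.344, 0.0982 and 0.397 in this order, and the cholesterol list had a median of -0.00058, a mean of 0.03 and an upward camera direction.

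Several of these metabolic calls depended on single libraries. PFKP lost its call without DMSO D6 or nifedipine B4 (adjusted p of at most 0.0572 in edgeR), and ME1 lost it without each library other than DMSO G3 (at most 0.131). HMGCS1 lost it without DMSO A2, DMSO D6, DMSO E10, nifedipine C1, nifedipine D12 or nifedipine G9, and STARD4 without DMSO D6, DMSO E10, nifedipine C1, nifedipine D7 or nifedipine G9 (at most 0.0870 in edgeR for each). Without nifedipine D7, 2 fatty acid oxidation genes and 2 fatty acid synthesis genes rose, and the camera adjusted p of fatty acid synthesis was 0.0215. That adjusted p was 0.0403 with library totals alone and 0.0267 with 1 surrogate variable, in a range from 0.0207 to 0.292 over the alternatives. The cholesterol mean was -0.0017 without nifedipine C1. Without DMSO G3 and nifedipine D7 together, the cholesterol mean was 0.09 with a camera adjusted p of 0.0102, in a range from 0.0102 to 0.913, fatty acid synthesis had 0.0207, and ME1 lost its call (adjusted p = 0.0561 in edgeR). With library totals alone PFKP and ME1 lost their calls (0.0764 and 0.0881 in edgeR), and 4 cholesterol and 3 fatty acid synthesis genes rose. In DESeq2 ME1 lost its call (adjusted p = 0.0630), 2 fatty acid synthesis genes rose and 2 glycolysis genes fell. ME1 also lost it with no filter (0.0705 in edgeR) and with the code number as a covariate (0.0554 in edgeR), a fit added after seeing the data.

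Stress and signalling lists without a camera call differed in their share of changed genes. Over all 15739 tested genes, 716 were called. Camera looks for a shift in one direction, so members that move in opposite directions can leave it without a call. Fry in a form that counts changes in either direction gave adjusted p-values over the 31 lists. These were 4.31e-09 for the unfolded protein list, 4.87e-04 for WNT, 0.00303 for NF-kB, 0.0454 for interferon and 0.719 for xenobiotic genes. Of 32 unfolded protein and integrated stress response genes, CANX (0.20) and DDIT4 (0.33) rose, ATF3 and PPP1R15A (-0.48) fell and 28 did not pass, and 4 rose and 3 fell adjusted over the list alone. This list's camera adjusted p was 0.996, pointing downward, with a median of 0.03 and a mean of -0.05. Of 13 WNT targets, the transcription factor gene TBX3 (0.42 ± 0.07, SE) and the ubiquitin ligase gene RNF43 (0.57 ± 0.13, SE) rose, 0 fell and 11 did not pass, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p 0.119). Without DMSO B9, 3 WNT targets rose and 1 fell. Without DMSO G3 and nifedipine D7 together, 1 rose, and RNF43 lost its call (adjusted p = 0.0698 in edgeR). Of 12 NF-kB and cytokine genes VCAM1 (0.24 ± 0.06, SE) rose, 0 fell and 11 did not pass, with 1 and 0 adjusted over the list alone (camera adjusted p 0.658, pointing upward; median 0.04, mean -0.01). In edgeR 0 of 12 xenobiotic and 0 of 17 interferon genes passed, over all genes or adjusted over the list alone, with camera adjusted p-values of 0.397 and 0.676. At an unadjusted p under 0.05 there were 0 xenobiotic genes, 2 higher interferon genes and 1 lower, and DESeq2 and limma-voom called 0 in either list. Without DMSO B9 1 interferon gene fell, and 1 rose without nifedipine C1 or with library totals alone.

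CANX lost its call without DMSO A2, DMSO D6, DMSO E10, nifedipine B4, nifedipine C1, nifedipine D12 or nifedipine G9 (adjusted p of at most 0.0871 in edgeR), and DDIT4 without each library other than DMSO E10 and DMSO G3 (at most 0.136). VCAM1 lost it without DMSO A2, DMSO D6, DMSO E10, nifedipine D7, nifedipine D12 or nifedipine G9 (at most 0.0916). Without DMSO G3 and nifedipine D7 together, DDIT4 and VCAM1 lost theirs (0.114 and 0.0639 in edgeR). Without DMSO G3, 5 genes of the stress response rose, and without DMSO B9 3 of them fell. The mean of NF-kB genes was 0.02 without DMSO D6. With library totals alone, or without DMSO G3 and nifedipine D7 together, 5 stress response genes rose, and in DESeq2 4 rose and 3 fell. DDIT4 also lost its call with no filter (0.0613 in edgeR) and with the code number as a covariate (0.0540 in edgeR), and VCAM1 in limma-voom (adjusted p = 0.0532).

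Genes with the highest fold among those named by size were of low abundance. LINC02395, a long non-coding RNA, rose from 1.203 ± 0.383 to 5.18 ± 1.12 CPM (SD, n = 5). APELA, which encodes a peptide ligand of the apelin receptor, rose from 1.62 ± 0.679 to 4.92 ± 1.73 CPM, the transcription factor gene FOXQ1 from 1.597 ± 0.308 to 4.06 ± 0.416 CPM and the heparan sulfate sulfotransferase gene NDST4 from 2.19 ± 0.332 to 5.24 ± 1.17 CPM (SD, n = 5 for each). SEMA3G, a secreted semaphorin, rose from 4.69 ± 1.01 to 9.83 ± 1.42 CPM (SD, n = 5). The others were BORCS8-MEF2B (1.69), XKRX (1.33), C1QL1 (1.304), LINC02268 (1.19), SP6 (1.09) and LINC00664 (1.06), as log2 changes. BORCS8-MEF2B is an annotated read-through that shares exons with its neighbours, so its value is uncertain. C1QL1 lost its call without DMSO D6 (adjusted p = 0.0538 in edgeR). Without DMSO G3 and nifedipine D7 together, XKRX and LINC02268 lost theirs (0.0547 and 0.0858 in edgeR).

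Among the steepest falls outside the lists were IL31RA (-2.48 ± 0.24, SE), a cytokine receptor gene, KRT80 (-2.09 ± 0.32, SE), LINC00702 (-1.43), ARID5A (-1.33), DUSP8 (-1.32), the epoxygenase gene CYP2J2 (-1.29) and KCNK3 (-1.29), which encodes the TASK-1 potassium channel. On GRCh38, NPPB (ENSG00000120937) lies on chromosome 1 from 11857464 to 11858931 on the minus strand, with NPPA (ENSG00000175206) from 11845709 to 11848345. RRAD (ENSG00000166592) lies on chromosome 16 from 66921679 to 66925644, NRAP (ENSG00000197893) on chromosome 10 from 113588716 to 113664127 and CSRP3 (ENSG00000129170) on chromosome 11 from 19182037 to 19210571. KCNS2 (ENSG00000156486) lies on chromosome 8 from 98427022 to 98432848, and LINC02395 (ENSG00000257771) on chromosome 12 from 49911953 to 49930320. RCAN1 (ENSG00000159200) lies on chromosome 21 from 34513142 to 34615142 and CACNA1C (ENSG00000151067) on chromosome 12 from 1970786 to 2697950. These spans are whole genes with introns and untranslated regions.

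**Figure D2:**
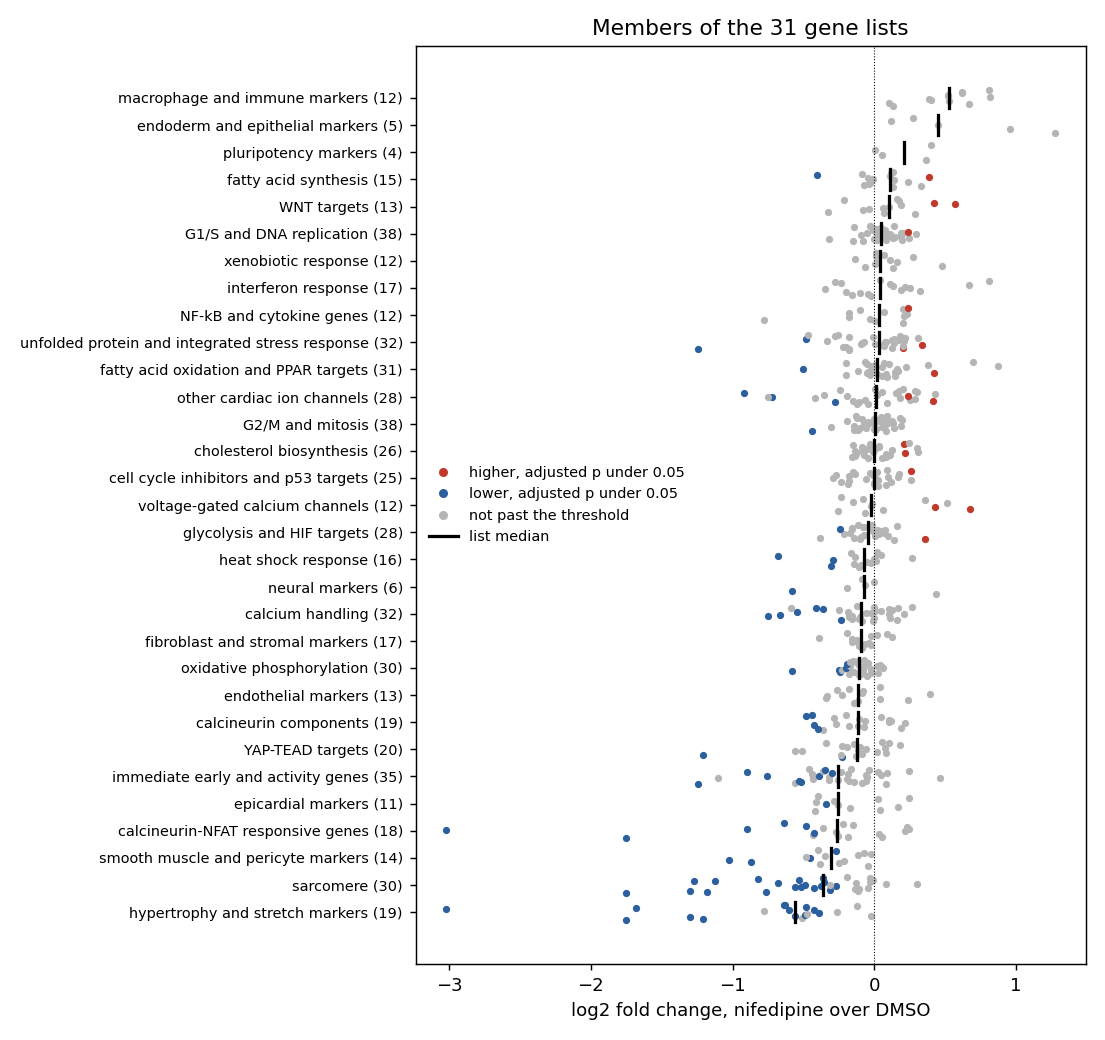
Log2 fold change of each measured member of the 31 gene lists, nifedipine over DMSO, with the number of members in brackets and a bar at each list median. The hypertrophy and stretch list has a median of -0.56, sarcomere -0.36 and smooth muscle and pericyte markers -0.31.

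Markers of other cell types gave few calls. In edgeR 0 of 17 fibroblast, 0 of 13 endothelial, 0 of 5 endoderm and 0 of 4 pluripotency markers passed, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 lower fibroblast markers, 1 higher and 2 lower endothelial markers, 2 higher endoderm markers and 1 higher pluripotency marker. DESeq2 called 0 in these lists, and limma-voom called 1 endoderm marker higher. Fibroblast markers had a median of -0.10 and endothelial markers -0.12, with camera adjusted p-values of 0.270 and 0.503, and the pluripotency value was 0.343. Endoderm and epithelial markers had a median of 0.45, a camera adjusted p of 0.0253 and an adjusted p of 0.242 with an estimated correlation. Of 11 epicardial markers the keratin gene KRT8 (-0.34 ± 0.09, SE) fell, 0 rose and 10 did not pass, and 2 fell adjusted over the list alone (camera adjusted p 0.0862). Of 6 neural markers MAP2 (-0.58 ± 0.10, SE) fell, 0 rose and 5 did not pass, with 1 that fell adjusted over the list alone (camera adjusted p 0.204).

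These marker results also rested on single libraries. The endoderm camera adjusted p was 0.0533 without DMSO A2, 0.0813 without DMSO B9, 0.135 without DMSO G3, above 0.05 without nifedipine B4, 0.0786 without nifedipine C1 and 0.108 without nifedipine G9. It was 0.0560 with library totals alone and 0.0950 with at least 50 counts, in a range from 0.00203 to 0.242 over the alternatives. The fibroblast list had a camera adjusted p of 0.0385 without DMSO B9 in a range up to 0.839, and a mean of 0.01 without DMSO G3. The epicardial list had one of 0.0154 without DMSO B9, 0.0388 without nifedipine C1 and 0.0424 with library totals alone, in a range up to 0.443. KRT8 lost its call without DMSO D6, DMSO E10 or any 1 of the nifedipine libraries (adjusted p of at most 0.128 in edgeR), with library totals alone (0.0679) and without DMSO G3 and nifedipine D7 together (0.0700), and with the macrophage level (0.0718) or code number (0.0659) as a covariate, and 2 epicardial markers fell without DMSO B9. Without DMSO B9 1 fibroblast marker fell, and without DMSO D6 1 endothelial marker rose. TUBB3, a neural marker with a value of -0.09 ± 0.14 (SE), was at 0.02 without DMSO G3 or nifedipine D7.

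Macrophage and immune markers varied between libraries within each condition. Their mean log2 CPM was -1.90 in DMSO G3 and -0.27 in DMSO A2 against 2.34 in DMSO D6, and -1.93 in nifedipine D7 against 2.53 in nifedipine D12. CD68, a lysosomal protein of macrophages, had 0 counts in DMSO A2, 2 in DMSO G3 and 184 in DMSO D6, and 10 in nifedipine D7 and 153 in nifedipine D12. The list median was 0.52, and in edgeR 0 of 12 members passed, over all genes or adjusted over the list alone, as did 0 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. The camera adjusted p was 0.152, and the adjusted p was 0.778 with an estimated correlation. Camera adjusted p was 0.00378 without DMSO D6 and 3.96e-04 without nifedipine D7, and reached 0.784 among the alternatives. It was 0.0162 without DMSO G3 and nifedipine D7 together. Without DMSO G3 and nifedipine D7 together, 191 genes of all those tested were higher and 512 lower.

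The first principal component of log2 CPM held 19.0% of the variance and the second 15.6%. On the first, DMSO libraries lay between -41.5 (G3) and 0.371 (D6) and nifedipine libraries between -3.93 (D7) and 24.3 (D12). Pearson correlations of log2 CPM, taken across genes, which are not independent replicates, had a median of 0.974 within groups and 0.971 between groups. The closest pair of libraries, nifedipine C1 and D12, differed with a chi-square of 2.59 per degree of freedom, so no library was counted as a repeat of another. TMM scaling factors were 0.980 ± 0.011 with DMSO and 1.02 ± 0.0052 with nifedipine (SD, n = 5; exact two-sided permutation p = 0.00794), the smallest p that 5 against 5 allow, and the groups did not overlap. The 20 most abundant genes of each library took 15.1% ± 0.504 of counts with DMSO and 14.5% ± 0.215 with nifedipine (SD, n = 5; exact two-sided permutation p = 0.0476). Values on the first component differed with an exact two-sided permutation p of 0.0238. Mitochondrial transcripts took 7.83% ± 0.657 of counts with DMSO and 7.74% ± 0.292 with nifedipine (SD, n = 5; exact two-sided permutation p = 0.778).

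**Figure D3:**
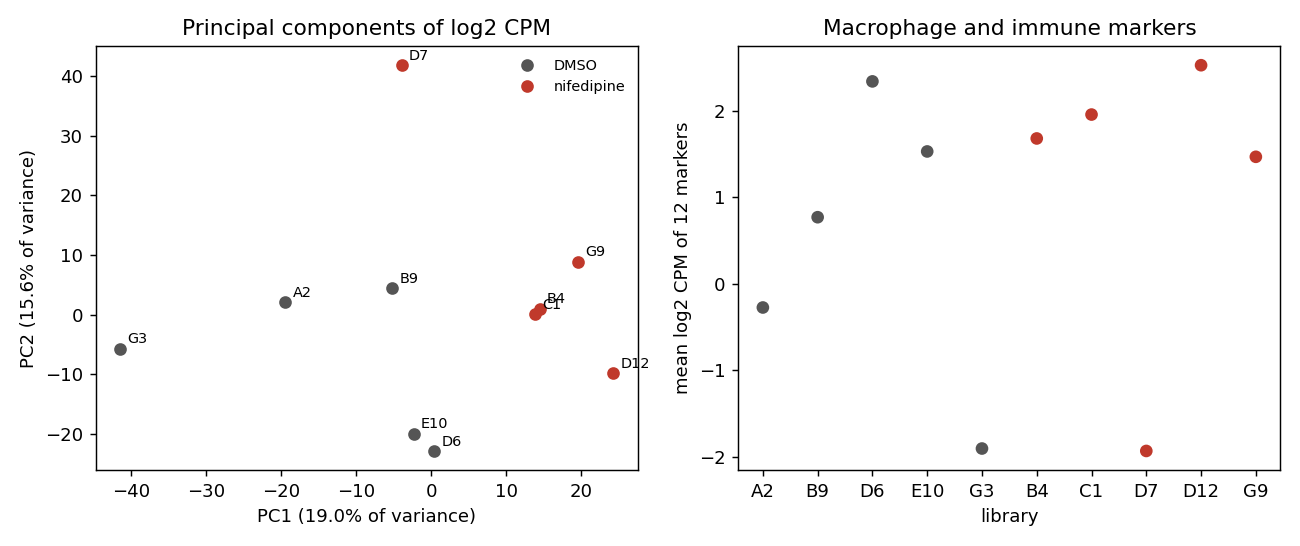
Left, the first and second principal components of log2 CPM for the 10 libraries, and right, the mean log2 CPM of 12 macrophage and immune markers in each library, by replicate code. DMSO G3 (-1.90) and nifedipine D7 (-1.93) have the lowest marker levels.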

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

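The tests of cardiomyocyte share, smooth muscle share, macrophage amounts, a macrophage response to nifedipine and SRF targets, and the fit with the macrophage level as a covariate, were chosen only after the result was seen. Of 126 possible divisions of the libraries into 5 and 5, 100 were drawn, the real one included, and 1 of them, the real one, called as many as 716 genes. The highest of the others called 34, which argues against a random division of these libraries as the source of the 716 calls. The other divisions mix DMSO and nifedipine libraries on each side, so the difference between conditions adds to their spread. Of these, 88 called 0 genes, so they are a weak comparison and do not exclude chance.

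In 260 sets of 5 values, which were library measures and named genes in each condition, 16 had 1 library whose gap to the next, over the range of the set, exceeded 0.71. That is 6.15%, where chance gives about 1 in 20. DMSO G3 was low for CACNA1C (gap over range 0.787), DUSP5 (0.735), CASQ2 (0.722), PFKP (0.774) and AJUBA (0.873), and high for COX7B (0.717) and CANX (0.965). DMSO A2 was low for JUN (0.769) and CENPE (0.738), DMSO E10 was low for CCND1 (0.734) and DMSO B9 was high for NEXN (0.732). Nifedipine D7 was high for SYNPO2L (0.733) and GPAM (0.864) and low for the mean macrophage marker level (0.763). Nifedipine G9 was high for AKAP6 (0.819) and nifedipine C1 for LSS (0.727).

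Macrophage markers differed between libraries of the same condition. Within groups the 12 markers rose and fell together, with a mean pairwise correlation of 0.841 against at most 0.257 in 1000 random lists matched on expression, and 11 further macrophage genes had 0.932, so macrophage-like cells in differing amounts are a candidate explanation; CD68 had 184 counts in DMSO D6 and CSF1R a mean of 5.83 CPM with DMSO. With the marker level as a covariate, 82.4% of called genes kept their call and sign, which argues against macrophage content as the source of most calls. Mean marker level differed by 0.65 on the log2 scale between conditions, with an exact permutation p of 0.540, and the list's mean change ran from 0.20 without nifedipine D12 to 1.26 without DMSO D6. A response to nifedipine stays open, because the spread between 5 libraries is too wide to exclude it.

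Sarcomere and hypertrophy genes, 46 in all, had a median log2 change of -0.48. A lower share of cardiomyocytes would lower sarcomere genes by a common factor if no other cells expressed them, which was not checked. The 95% interval left out the list median for 21 of 30 members (10 above and 11 below). That argues against a lower share as the whole cause only under this condition, and the intervals may be too narrow. With library totals alone the median was -0.42. That scaling moved the median gene by only 0.06, so it could not have removed the fall and cannot test other scaling errors. After a trend on GC content and transcript length was removed the median was -0.44, which argues against GC content and length as the cause. A small change in cell share beside a response to nifedipine stays open.

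Smooth muscle and pericyte markers had a median log2 change of -0.31. An equal loss of both cell types would lower the 14 members alike if no other cells expressed them, which was not checked. Of these members, 5 had a 95% interval that left out the list median. That argues against such an equal loss as the whole cause only under this condition, and the intervals may be too narrow. A loss of smooth muscle cells alone was not tested and stays open. As a hypothesis, these markers may follow lower transcripts of targets of the transcription factor SRF: 26 other targets had a median of -0.28, with 15 lower, 0 higher and a camera p of 0.00373 with an estimated correlation, and SRF itself fell by 0.59 (SE 0.06). That list was written after the gene values were seen, so this explanation cannot be told apart from chance selection of its members.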

How the results depend on the processing

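The fits without DMSO G3 and nifedipine D7, and with the macrophage level or code number as a covariate, were chosen after seeing the data. Of 79 named genes past the threshold, 0 changed sign in the alternatives run and 57 kept their call in each one other than the test against a fold of 1.2. That test asks for a change beyond 1.2-fold, and 40 of the named genes lost their call in it. RCAN1, MYH7, MYOZ2, AKAP6, SLC8A1, CACNA1D and CACNA1G were among them. Of all calls, 20.1% were kept in it. Higher and lower genes numbered 521 and 304 with library totals alone, which moved the median gene by 0.06. They numbered 380 and 721 with no filter, where more genes were tested, 23 and 121 against a fold of 1.2, and 96 and 273 at an adjusted p under 0.01, with 416 higher at 0.1. Leaving out 1 library gave 156 to 333 higher and 337 to 518 lower genes. Lists past the threshold numbered 11, against 3 with an estimated correlation and 10 to 14 with 1 library left out. No paired analysis was run, because the labels give no pairing of libraries. The codes name single libraries, so they do not show whether libraries of the 2 conditions shared a culture. At this depth the simulation recovered 65.0% of genes changed 1.5-fold.

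Sign changes among these results came in lists and genes that had not passed the test, and the cause was not tested. With library totals alone the mean log2 change was 0.011 for other cardiac ion channels, 0.048 for G2/M, 0.042 for cell cycle inhibitors, 0.017 for glycolysis, 0.0066 for the unfolded protein response, 0.047 for NF-kB, 0.015 for MYH6 and 0.023 for TNNT2. With at least 50 counts it was 0.0043 for other cardiac ion channels, 0.0035 for G2/M and 0.056 for NF-kB. With 1 surrogate variable it was 0.012 for cell cycle inhibitors, 0.0053 for NF-kB and 0.026 for TUBB3. Without DMSO G3 and nifedipine D7 it was 0.030 for cell cycle inhibitors, 0.024 for the unfolded protein response, 0.030 for fibroblast and 0.043 for neural markers, -0.036 for CACNA1C and 0.117 for TUBB3. With the macrophage level as a covariate it was -0.102 for macrophage markers, which that covariate removes. With 1 library left out it ran from -0.032 to 0.022 for G2/M, -0.035 to 0.012 for cell cycle inhibitors, -0.0017 to 0.062 for cholesterol biosynthesis, -0.110 to 0.019 for NF-kB, -0.143 to 0.014 for fibroblast markers, -0.107 to 0.00020 for TNNT2 and -0.177 to 0.015 for TUBB3.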

Other observations

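The 8 gene families below and their tests were chosen only after the result was seen, so they describe these libraries. Their p-values are adjusted over the 8 families, which does not correct for picking families by their values. These results cannot be told apart from chance selection. Caveolins and cavins, which shape plasma membrane caveolae, were lower: 5 of 7 fell, with CAVIN4 at -0.68, CAVIN1 at -0.45, CAV2 at -0.40, CAVIN3 at -0.37 and CAV1 at -0.30 (camera adjusted p of 0.00170 with an estimated correlation). PDZ-LIM and FHL proteins, many of which bind actin or the Z-disc, had 7 of 9 that fell and a median of -0.39 (camera adjusted p of 2.16e-04 with an estimated correlation). Of these 7, FHL1 and FHL2 are also in the hypertrophy list and PDLIM5 in the sarcomere list, so the family partly repeats those lists. Among 11 tubulins TUBB6 (-0.47), TUBB4B (-0.28), TUBA1A (-0.33) and TUBB2A (-0.53) fell (camera adjusted p of 0.0191 with an estimated correlation). Medians with library totals alone were -0.35 for caveolins and cavins, -0.33 for PDZ-LIM and FHL proteins and -0.22 for tubulins. PDLIM1 lost its call without DMSO D6, DMSO E10, nifedipine B4 or nifedipine C1 (adjusted p of at most 0.0687 in edgeR) or with library totals alone (0.0705), and FHL3 without DMSO A2, DMSO D6, DMSO G3, nifedipine B4 or nifedipine G9 (at most 0.0892) or with library totals alone (0.0554). CAVIN3 lost its call without DMSO A2, DMSO D6, nifedipine D7, nifedipine D12 or nifedipine G9 (adjusted p of at most 0.0852 in edgeR) or with library totals alone (0.0612), and TUBB2A without each library other than DMSO B9 and nifedipine C1 (at most 0.106).

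Some phosphodiesterase and sodium channel genes rose. Of 19 phosphodiesterase genes, the cAMP-specific PDE4B (0.94 ± 0.10, SE) and PDE4D (0.37 ± 0.08, SE), PDE1C (0.43 ± 0.10, SE) and PDE11A (0.83 ± 0.24, SE) rose and PDE10A (-0.41 ± 0.08, SE) fell, with a camera adjusted p of 0.0696 with an estimated correlation. PDE1C lost its call without DMSO D6 or nifedipine G9 (adjusted p of at most 0.0571 in edgeR) and PDE11A without each library other than DMSO D6 (at most 0.119). Of 6 voltage-gated sodium channel alpha subunits, SCN1A (1.51 ± 0.34, SE) and SCN8A (0.61 ± 0.13, SE) rose (camera adjusted p of 0.0191 with an estimated correlation). Of 20 dual specificity phosphatases 4 fell (0.0191 in the same test). Among these 4, DUSP1 and DUSP5 are also in the immediate early list, so the family partly repeats that list. Of 10 histone deacetylases HDAC5 and HDAC9 fell (0.170 in the same test), and of 20 semaphorins 3 rose and 1 fell (0.215). HDAC9 lost its call without each library other than DMSO E10 and DMSO G3 (adjusted p of at most 0.101 in edgeR) and with library totals alone (0.137). MAP2K6, a kinase upstream of p38, rose from 20.4 ± 0.569 to 39.8 ± 4.27 CPM (SD, n = 5), and the imprinted gene PEG10 from 150.0 ± 19.0 to 286 ± 38.2 CPM (SD, n = 5).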
